A study of Homo sapiens with 6 samples.

How the data were processed

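Gene expression was measured on 6 one-colour Affymetrix arrays hybridised with biotin-labelled material made from total RNA of U87 MG cells, an established human glioblastoma line. Per the labels, 3 arrays came from cells with stable overexpression of GUCY1B3, the beta subunit of soluble guanylate cyclase, and 3 from U87 MG cells used as the control. The labels name no empty-vector line among the controls. The design therefore cannot tell effects of GUCY1B3 from other differences between the stable and the control cells. The labels also do not say whether the replicates were separate cultures. Every p-value thus measures the spread between these arrays, which may be technical. No treatment was applied and the cells were grown in DMEM with serum, per the labels' protocols.

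The authors deposited 1 table of log2 expression values for 70523 features. Per the submitters' processing notes and the sample descriptions, the values came from RMA in Affymetrix Expression Console, a procedure that corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The software version, the library files and the genome build of the array were not given in the sources used here. The scanner files were not used here, and neither were detection calls, so no probe set was called present or absent. The medians of the 6 arrays over all features lay between 4.97 and 5.03, and the highest values between 14.19 and 14.25. The number of arrays limits the precision of each value.

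Gene names came from the platform annotation supplied with the table. It gave 1 symbol for 23781 probe sets, several symbols for 1543 and none for the other 45199 features, which are unnamed here. Symbols were looked up in the RefSeq gene table of GRCh38.p14. They were found through Entrez identifiers for 21497 probe sets, by symbol for 1974 and by synonym for 306, and 4 were kept as given. The symbol changed for 306 probe sets. GUCY1B3 is listed under its current symbol, GUCY1B1. The chromosome given beside a named probe set was read from its identifier. No coordinates are given, because the array's build is not named. The RefSeq table served for names, for leaving out Y-linked genes, and for the chromosome and order of genes in the chromosome tests.

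For each of the 22411 genes with its own probe set, the probe set with the highest mean over the 6 arrays was kept. A gene was tested when its value exceeded the median of all features of that array on at least 3 of the 6 arrays, which left 15823 genes. Overexpression was compared with control by limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The residual degrees of freedom were 4, and eBayes added 4.38 prior degrees of freedom. Differences are overexpression minus control on the log2 scale, and errors beside group means are SD over 3 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the annotation, the chromosome tests and the plots.

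Before the data were examined, 39 gene lists (1027 entries) were fixed. They covered signalling pathways, matrix, stress and cell cycle genes, and markers of other cell types. Of the entries, 920 matched a probe set with 1 symbol. The lists with at least 5 tested members, 38 in all, were compared with the remaining genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The mitochondrially encoded genes were not tested, since 0 of their 13 members lay on a probe set with 1 symbol. Counts of list members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

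The named genes followed a rule fixed before the data were examined. It took the cyclase subunits, and the 12 genes with the greatest rise and the 12 with the greatest fall among those past the threshold whose 3 arrays of one group all lay above those of the other. Genes with only locus-style names, Y-linked genes and XIST were left out. From each list it took up to 4 members past the threshold with the greatest difference, or the member with the smallest p where none passed. Genes named outside this rule are marked as chosen after their values were seen.

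The procedure was tested on simulated data with the means of these arrays and the spreads moderated by eBayes for 15823 genes. It recovered 66 of 67 genes changed by 0.5 (98.5%), 67 of 67 changed by 1 and 66 of 66 changed by 2 on the log2 scale. Of its 206 calls, 7 were unchanged genes (3.40%). The list test called the 1 list shifted by 0.3 and 0 of 37 lists that were not shifted. The simulated noise was drawn independently for each gene and array. These results therefore do not cover genes that vary together or an array that stands apart. Genes with a large spread of their own were simulated with the smaller moderated one, so recovery may be overstated for them.

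The alternatives were the replicate number as a block, no filter and a stricter filter on dim probe sets (the 75th percentile), the mean of a gene's probe sets, all features as deposited, 3 further normalizations (median centring, quantile and cyclic loess), limma with trend and robust settings, an ordinary equal-variance test, array quality weights, each array left out in turn, and an adjusted p under 0.01. Removal of the running median over the 40 nearest genes on the chromosome, and list counts without control array 3, were added after the data were seen.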

Results

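The data set held log2 RMA expression values for 3 arrays of U87 MG cells stably overexpressing GUCY1B3 and 3 arrays of control U87 MG cells. Soluble guanylate cyclase, the receptor for nitric oxide, is made of an alpha and a beta subunit and converts GTP to cGMP. The comparison asked which transcripts differed between the overexpressing line and the control cells. It cannot assign a difference to GUCY1B3 itself, since no vector control was named. Pearson correlations between arrays across the 15823 tested genes, which are not independent replicates, lay between 0.982 and 0.997.

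GUCY1B3, the overexpressed gene, was higher on all 3 overexpression arrays. Its probe set on chromosome 4 (GUCY1B1, TC04000788.hg.1) read 8.10, 8.18 and 8.40 on the overexpression arrays and 7.45, 7.70 and 7.49 on the control arrays. The means were 8.23 ± 0.16 and 7.55 ± 0.13 (SD, n = 3 each), a difference of 0.68 on the log2 scale or 1.60-fold (limma, adjusted p = 0.00431). With an ordinary equal-variance test per gene the adjusted p was 0.0785. Whether the probe set covers the coding sequence on the plasmid is not known, so the 1.60-fold rise may not measure the overexpression achieved. If the probe set covers it, plasmid transcripts cannot be told from those of the cells' own gene. The other subunits were dim and differed little. GUCY1A1, the main alpha subunit, read 4.10 ± 0.02 against 4.04 ± 0.05, GUCY1A2 4.44 ± 0.02 against 4.45 ± 0.04 and GUCY1B2 4.24 ± 0.02 against 4.18 ± 0.05 (SD, n = 3 each). These 3 did not pass the filter on dim probe sets, and without that filter their adjusted p lay at 0.566, 0.919 and 0.581.

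Among the tested genes, the strongest differences between the stable line and the control cells were falls in expression. Of 15823 genes, 1010 were higher and 717 lower in overexpression (limma, adjusted p under 0.05), against 726 higher and 855 lower with each array centred on its median and 630 higher and 612 lower with the regional median removed, and among changes of at least 2-fold 7 were higher and 39 lower. The deepest fall was that of GABRA3, a GABA-A receptor subunit on the X chromosome, from 8.34 ± 0.09 to 4.63 ± 0.03 (SD, n = 3 each), 13.1-fold lower (adjusted p = 3.96e-08). SULT1B1, a sulfotransferase, fell by 3.22 on the log2 scale (adjusted p = 0.000475), and the collagenase MMP1 fell from 10.02 ± 0.53 to 7.10 ± 0.10, 7.57-fold (adjusted p = 0.000332). The zinc finger gene ZNF512 fell by 2.25 (adjusted p = 6.51e-07).

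The other genes among the greatest falls were named for the size of their fall, not as a functional group. In the fixed list of inflammatory cytokines and NF-kB targets, 0 of 22 tested genes were higher and 1, PTGS2, was lower. With all arrays that list was not shifted (camera, adjusted p = 0.0675). PTGS2, the inducible cyclooxygenase, fell by 2.60 (adjusted p = 0.0350), the stromelysin MMP3 was 5.16-fold lower (adjusted p = 0.0157), complement C3 5.01-fold lower (adjusted p = 0.0281) and the EGFR ligand EREG 4.34-fold lower (adjusted p = 0.00988). FDCSP, a small secreted peptide, fell by 2.23. The desmosomal cadherin DSG2 was 3.58-fold lower and the laminin receptor subunit ITGA6 3.55-fold lower. The pseudogene FABP5P7 fell by 1.80, but it shares sequence with FABP5 and its probe set cannot be assigned to 1 of them with certainty. The values of PTGS2, MMP3, C3, EREG and FDCSP varied among the control arrays, with control array 3 the lowest. PTGS2 read 8.90, 7.90 and 5.82 on control arrays 1 to 3 and 4.80, 4.95 and 5.07 on the overexpression arrays. The size of the fall depended on the control arrays used. For PTGS2 the difference was -3.46 without control array 3 and -1.92 without control array 1, and for C3 it was -3.05 and -1.87. With the ordinary equal-variance test the adjusted p was 0.227 for PTGS2, 0.163 for MMP3, 0.206 for C3, 0.136 for EREG and 0.104 for FDCSP. Leaving out any 1 array except control array 3 ended the calls of PTGS2 and C3, leaving out any 1 overexpression array ended that of MMP3, and leaving out overexpression array 1 or 2 ended that of EREG. The overexpression means of GABRA3, SULT1B1, ZNF512, FDCSP, DSG2 and PTGS2 lay below the medians of all features on the arrays, so the folds depend on the array's background.

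Rises were smaller. The hair keratin-associated genes KRTAP1-5 and KRTAP1-1 rose 3.63-fold and 2.43-fold, from 7.72 ± 0.15 to 9.58 ± 0.17 and from 7.92 ± 0.19 to 9.20 ± 0.15 (SD, n = 3 each). The protocadherin PCDHGB2 rose 2.89-fold. These genes belong to families of near-identical sequence, so the assignment to a member is uncertain. CTSK, which encodes the lysosomal protease cathepsin K, rose 2.33-fold (adjusted p = 0.00651) and GPNMB, a glycoprotein of lysosomes and melanosomes, 2.09-fold (adjusted p = 0.00103). BEX1 rose 2.15-fold, CD22, a sialic acid-binding lectin, 2.03-fold and the lectin-like CLEC2B 1.98-fold. The endocytic adaptor EPS15 and the kinase WNK3 each rose 1.91-fold, the LIM protein AJUBA 1.89-fold and GLUL, glutamine synthetase, 1.87-fold.

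**Figure D1:**
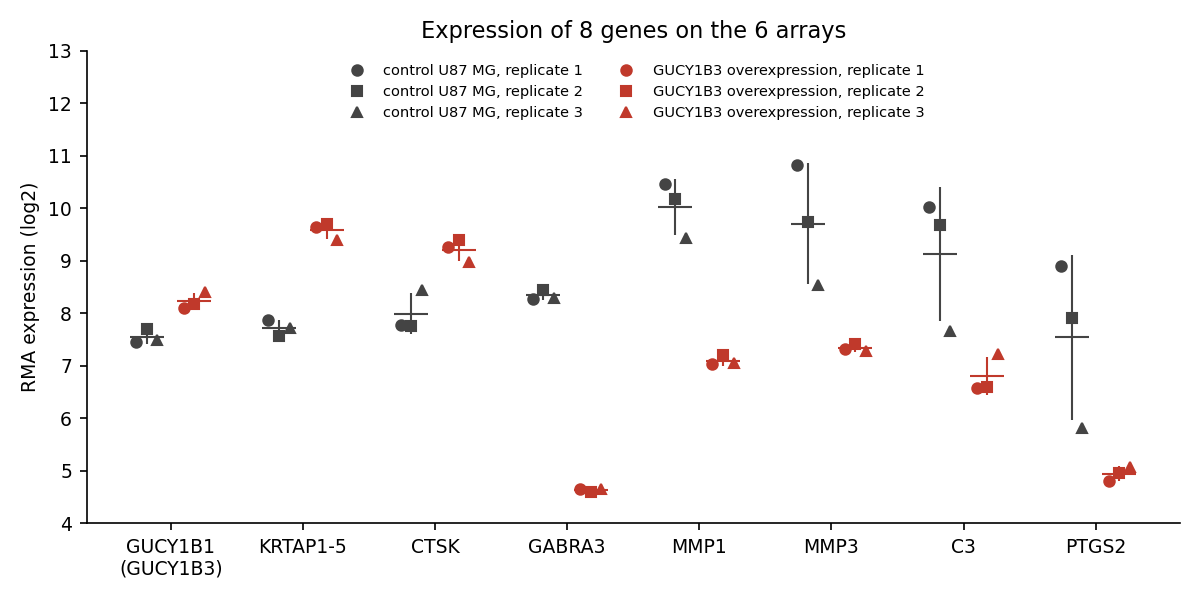
RMA expression (log2, vertical axis) of 8 genes on the 3 control arrays (grey) and the 3 GUCY1B3 overexpression arrays (red); symbols mark replicates, horizontal bars the group mean and vertical lines the SD. GUCY1B1 (GUCY1B3) rose by 0.68 and GABRA3 fell by 3.71, while MMP3, C3 and PTGS2 were lowest among the controls on control array 3.

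In all, 3957 genes had an unadjusted p under 0.05, and in 29.2% of genes the 3 arrays of one group all lay above those of the other, against 10% by chance. The split of calls depended on the centring of the arrays. Of the called genes 58.5% were higher, against 45.9% after each array was centred on its median (726 higher and 855 lower), the median difference of all tested genes being 0.02 before and -0.01 after. The counts moved when 1 array was left out. Without overexpression arrays 1, 2 and 3 in turn, 334, 306 and 433 genes were higher and 215, 262 and 297 lower. Without control array 1, 562 were higher and 460 lower, and without control array 3, which stood apart from the other controls, 2053 were higher and 1577 lower.

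Of 19 tested genes of cholesterol biosynthesis 5 were higher and 0 lower, or 13 higher when adjusted over the list alone. The median difference was 0.21 (camera, adjusted p = 4.29e-05 with the preset correlation and adjusted p = 0.994 with an estimated correlation). LSS, lanosterol synthase, rose 1.65-fold (8.74 ± 0.01 against 8.02 ± 0.17, SD, n = 3 each) and DHCR7, the last enzyme of the pathway, 1.63-fold. IDI1 rose by 0.37 and MSMO1 by 0.30. Control array 3 lay 0.13 above the other controls in the list's median, and without it 11 members were higher and 0 lower.

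Of 26 tested targets of the tumour suppressor p53 7 were higher and 1 lower, or 9 and 1 when adjusted over the list alone, with a median difference of 0.16 (camera, adjusted p = 0.00170 with the preset correlation and adjusted p = 0.994 with an estimated correlation). The translesion polymerase POLH rose by 0.52, the stress cytokine GDF15 by 0.49, the repair protein DDB2 by 0.47 and the cell cycle inhibitor CDKN1A by 0.26, whereas SPATA18 fell by 0.53. Without overexpression array 2 the list's adjusted p was 0.0653. Without control array 3, 11 members were higher and 1 lower.

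MAPK immediate early and feedback genes, and receptor tyrosine kinases with their ligands, had medians below 0, and both calls were lost with an estimated correlation (adjusted p = 0.994 each) and under each of the 3 further normalizations. In the MAPK list 0 of 24 members were higher and 3 lower, over all genes and over the list alone, with a median difference of -0.16 (camera, adjusted p = 0.0373). FOSL2 fell by 0.59, and the pathway inhibitors SPRY2 and SPRED1 fell by 0.41 and 0.25. In the receptor list 1 of 26 members was higher and 2 lower, or 2 and 5 over the list alone, with a median of -0.13 (adjusted p = 0.0373). EREG and TYRO3 were the members that fell, TYRO3 by a difference of -0.26, and EPHA4 rose by 0.55. The MAPK call also ended without overexpression array 1 (adjusted p = 0.0534), overexpression array 2 (0.0836), control array 1 (0.188) or control array 2 (0.343), and the receptor call without overexpression array 2 (0.0836), control array 1 (0.0878) or control array 2 (0.244). Control array 3 lay 0.28 below the other controls in the median of the MAPK list (its difference was -0.28), and without that array 1 MAPK gene was higher and 14 lower.

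**Figure D2:**
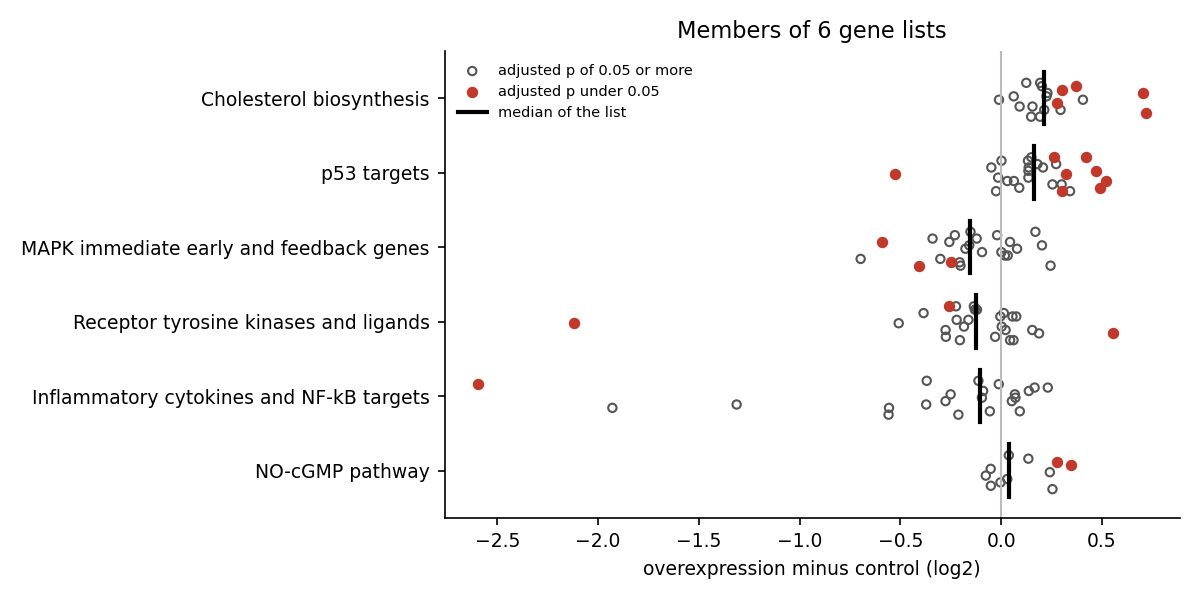
Difference between overexpression and control (log2, horizontal axis) of the tested members of 6 gene lists; each circle is a gene, filled where its adjusted p was under 0.05, and vertical bars mark list medians. The medians were 0.21 for cholesterol biosynthesis, 0.16 for p53 targets, -0.16 for MAPK genes, -0.13 for receptor tyrosine kinases, -0.10 for inflammatory genes and 0.04 for the NO-cGMP pathway.

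In the NO-cGMP pathway, the list nearest to the overexpressed gene, 2 of 11 tested members rose and 0 fell, in the whole table and over the list alone. ABCC5, which exports cyclic nucleotides, rose by 0.35 (adjusted p = 0.0128) and PRKG1, the cGMP-dependent kinase, by 0.28 (adjusted p = 0.0148). The list was not shifted against other genes (median 0.04, camera adjusted p = 0.390), while fry, which does not compare it with other genes, gave an adjusted p of 0.0424.

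Inflammatory cytokines and NF-kB targets held 22 tested genes, of which 0 were higher and 1, PTGS2, was lower (0 over the list alone; median -0.10, camera adjusted p = 0.0675). Control array 3 lay below the other controls by a median of 0.59 (its difference was -0.59), and without it 0 members were higher and 11 lower and the list was shifted (adjusted p = 1.22e-06). In the hypoxia list 0 of 27 members were higher and 2 lower in both adjustments. The carbonic anhydrase CA12 fell by 1.47 and adrenomedullin, ADM, fell by 0.35 (median -0.05, camera adjusted p = 0.0675). Control array 3 differed from the other controls by a median of -0.10 in this list, and without it 2 members were higher and 12 lower and the list was shifted (adjusted p = 0.00110).

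Genes of the extracellular matrix and its receptors moved both ways. Of 24 collagens 0 rose and 3 fell, also when adjusted over the list alone. COL6A3 fell from 10.23 ± 0.12 to 9.12 ± 0.05 (SD, n = 3 each), COL8A1 fell by 0.61 and COL1A2 fell by 0.60. Of 26 matrix glycoproteins 1 rose and 6 fell (3 and 8 adjusted over the list alone). The fibrillin FBN1 was 2.02-fold lower, the laminin chain LAMA4 fell by 0.84, THBS2 fell by 0.73 and tenascin, TNC, fell by 0.70. Of 26 matrix proteases and inhibitors 3 rose and 3 fell (3 and 5 over the list alone). Besides MMP1 and MMP3, the gelatinase MMP2 fell by 0.88 and ADAMTS5 rose by 0.61. Of 22 integrins 1 rose and 2 fell, also over the list alone, and ITGAV fell by 0.70 beside ITGA6 while ITGA4 rose 1.83-fold. In all 4 lists the median lay above 0 (0.04, 0.02, 0.01 and 0.02), but those of glycoproteins and proteases lay below 0 under each of the 3 further normalizations and that of integrins with centring and cyclic loess. The mean (-0.06, -0.14, -0.20 and -0.05) and the direction of the test lay below 0, and with all arrays none was shifted (camera adjusted p = 0.692, 0.235, 0.524 and 0.778). Control array 3 differed from the other controls by medians of -0.13 in collagens and -0.12 in proteases, and without it 6 collagens, 8 glycoproteins, 6 proteases and inhibitors and 5 integrins were lower and the glycoprotein list was shifted (adjusted p = 0.0291).

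Among ligands and growth factors, 2 of 23 TGF-beta genes rose and 6 fell (2 and 7 adjusted over the list alone). The activin antagonist FST fell by 1.53, LTBP1 fell by 0.74, BMP2 fell by 0.72 and CCN2 rose by 0.61. FST read 9.37, 9.38 and 7.98 on control arrays 1 to 3, and leaving out any 1 array except control array 3 ended its call. Of 22 angiogenic factors 3 rose and 3 fell (4 and 4 over the list alone). HGF fell from 9.06 ± 0.44 to 7.44 ± 0.32 (SD, n = 3 each), the semaphorin receptor NRP2 fell by 0.57, SEMA3C fell by 0.51 and KITLG rose by 0.56. Of 26 Wnt genes 3 rose and 3 fell, also over the list alone. WNT5A was 2.67-fold lower (adjusted p = 0.000617), the co-receptor LRP6 fell by 0.53, and the antagonists DKK3 and DKK1 rose by 0.76 and 0.54. Of 20 YAP/TAZ targets 4 rose, among them AJUBA, CCN2 and GADD45A (0.32), and 1, TGFB2, fell by 0.45 (5 and 1 over the list alone). In the Notch list 0 of 19 rose and 1, HEY1, fell by 0.25, also over the list alone. These lists were not shifted (camera adjusted p between 0.256 and 0.984). Control array 3 differed from the other controls by medians of -0.06 in TGF-beta genes and -0.09 in angiogenic factors. Without it 4 TGF-beta genes were higher and 9 lower, and 4 angiogenic factors were higher and 8 lower. The Wnt median (0.02, below 0 under each of the 3 further normalizations) differed in sign from its mean (-0.02) and test, and the YAP/TAZ median (-0.01) from its mean (0.05) and test.

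Cell cycle lists changed little with all arrays. Of 51 G2/M genes 5 rose and 1 fell, also when adjusted over the list alone, with G2E3 up by 0.51, UBE2C by 0.40, ANLN by 0.37 and HMGB2 by 0.34. Of 39 S-phase genes 3 rose and 2 fell (4 and 2 over the list alone). The chromatin assembly factor CHAF1B rose by 0.44 and the uracil glycosylase UNG by 0.32, and TIPIN fell by 0.37 and CDCA7 fell by 0.25. Among cyclins and their partners 2 of 24 rose and 3 fell (2 and 4 over the list alone). CCNE1 rose by 0.43, CDK6 fell by 0.40 and RB1 fell by 0.27. Of 13 replication-dependent histones 0 passed the threshold of limma in either adjustment, 3 were higher at an unadjusted p under 0.05 and 0 were called by the ordinary test. H2AC13 had the smallest p, with 6.02 ± 0.02 against 5.83 ± 0.14 (SD, n = 3 each). The camera adjusted p of these 4 lists were 0.425, 0.945, 0.987 and 0.235. Control array 3 lay above the other controls by medians of 0.29 in G2/M genes, 0.24 in S-phase genes and 0.28 in histones. Without it 17 G2/M genes rose and 1 fell, 12 S-phase genes rose and 2 fell, and 7 histones rose, and these 3 lists were shifted (adjusted p = 7.14e-05, 0.0225 and 0.000457).

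Of 24 type I interferon response genes 6 rose and 4 fell, also when adjusted over the list alone. IFI44L and IFI44 fell by 1.13 and fell by 0.81, and IFITM3 and IFIT3 rose by 0.57 and 0.41. The list's mean (-0.01) differed in sign from its median (0.02, below 0 under each of the 3 further normalizations) and test. Of 13 NRF2 targets 2 rose and 0 fell (3 and 1 over the list alone), the thioredoxin reductase TXNRD1 by 0.48 and the ferritin chain FTL by 0.36. Of 17 glycolysis genes 1, PFKL, rose by 0.41 and 2 fell, HK2 and PKM, which fell by 0.26 and fell by 0.19 (the same counts over the list alone). Among 26 genes of the unfolded protein and ATF4 response PHGDH rose by 0.38 and SLC7A5 fell by 0.59 (1 and 1 over the list alone), and control array 3 differed from the other controls there by a median of -0.11. Of 25 apoptosis regulators 1, BCL2, rose by 0.33, and of 18 antigen presentation genes 1, CIITA, rose by 0.33 (0 of each over the list alone). Of 16 heat shock genes 0 passed the threshold of limma in either adjustment, 1 was lower at an unadjusted p under 0.05 and 0 were called by the ordinary test, and HSPH1 had a difference of -0.22. Of 25 ribosomal protein genes 0 passed, 3 were higher and 3 lower at an unadjusted p under 0.05 and 1 was called by the ordinary test, and RPS28 had a difference of -0.14. The camera adjusted p of these 8 lists lay between 0.390 and 0.984.

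Markers of cell identity gave no common direction. Among 14 astrocyte markers GLUL and the glutamate transporter SLC1A3 (0.46) rose and the connexin GJA1 fell by 1.05. Among 15 glioma stem cell and progenitor genes NES rose by 0.53 and L1CAM by 0.74, while ITGA6 and HEY1 fell. In the mesenchymal list of 15 L1CAM rose and FOXC2 fell by 0.59. ACTA2 and CNN1 rose by 0.52 and 0.35 and MCAM fell by 0.25 among 16 pericyte and smooth muscle markers. UCHL1 fell by 0.43 among 12 neuron markers, and CLDN7 rose by 0.34 among 14 epithelial markers. No other member of these 6 lists was called, and the counts adjusted over the list alone were equal. COL1A2 was the 1 of 8 fibroblast markers that fell (2 over the list alone). Control array 3 differed from the other controls by a median of -0.17 in the fibroblast list, and without that array 0 of its members were higher and 2 lower. In 3 lists limma called 0 genes in either adjustment and the ordinary test 0. Among 13 oligodendrocyte lineage markers 2 were higher and 2 lower at an unadjusted p under 0.05, and PDGFRA had the smallest p (-0.38). Among 11 endothelial markers 1 was higher at that level, KDR (0.19), and among 12 leukocyte and microglia markers 0, with C1QC at 0.11. The camera adjusted p of these 10 lists lay between 0.425 and 0.987. The median of the stem cell list (0.02, below 0 under each of the 3 further normalizations) differed in sign from its mean (-0.05) and test, and so did that of the oligodendrocyte list (0.02, below 0 with centring and cyclic loess, mean -0.0018).

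Genes past the threshold also lay in runs along the chromosomes. The regions, and the genes named at their ends, were chosen after the data were seen. A running median over 41 tested genes was compared with a bound that 95% of 100 shuffled genomes stayed within. Stretches beyond the bound were joined where they lay at most 40 genes apart, and joined stretches of at least 20 genes were kept. This gave 10 regions with 826 of 15793 placed genes and 16.4% of the called genes, and the running median lay beyond the bound at 692 of the 826. On chromosome 14 the region from SUPT16H to STYX held 163 tested genes with a median difference of 0.20, 63 of them higher and 3 lower. On chromosome 7 the region from TMEM184A to UPP1 held 197 genes with a median of 0.16, 66 higher and 2 lower, and on chromosome 21 that from RWDD2B to SIK1 held 95 with a median of 0.14, 22 higher and 0 lower. On chromosome 4 the region from TAPT1-AS1 to RNA5SP162 held 87 genes with a median of -0.25, 2 higher and 39 lower, and on chromosome 15 that from TUBGCP4 to C2CD4B held 93 with a median of -0.19, 1 higher and 31 lower. Single arrays compared with the other 2 of their group gave 0 to 7 regions and at most 288 genes in them. The genes named above were grouped by list without regard to these regions. With the regional median removed, 19 named genes were past the threshold no longer.

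**Figure D3:**
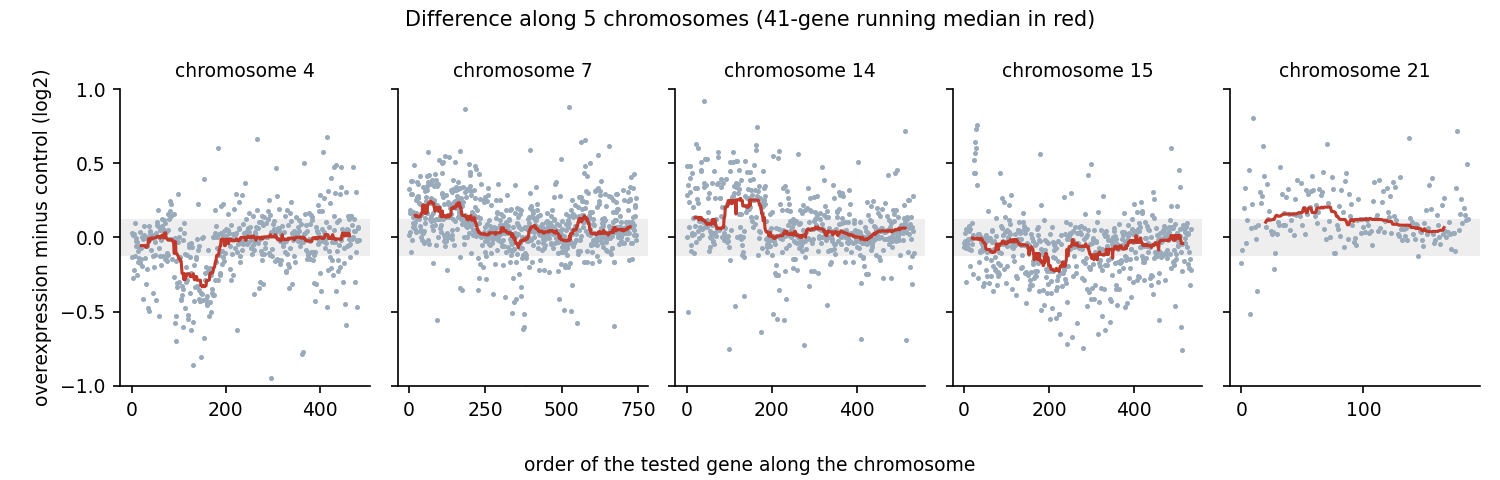
Difference between overexpression and control (log2, vertical axis) of the tested genes in their order along 5 chromosomes (horizontal axis); dots are genes, the red line is the running median over 41 genes, the grey band is the bound from shuffled genomes, and 15 genes lie beyond the axis. The line leaves the band downward on chromosomes 4 and 15 and upward on chromosomes 7, 14 and 21.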

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

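The tests chosen only after the result was seen were the regions of the running median, the share of genes still called once the regional median was removed, the tests of control array 3, the count of splits at 2-fold, the comparison of each array with the other 2 of its group, the comparison of 1 array with 2 of the other group, and the final form of the trend test, which replaced one that changed no sign, besides the lysosomal, symbol family and SNORD116 tests among the other observations. The mixture test was first limited to genes past the threshold and was then widened to all genes at least 2-fold apart.

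Signals appeared among features that the gene comparison did not use. Of 15482 tested transcript clusters without a symbol, 219 were higher and 152 lower in overexpression, of which 19 were at least 2-fold higher and 30 at least 2-fold lower. Of 1152 tested probe sets with several symbols, 57 were higher and 33 lower, and 1 was at least 2-fold higher. Over all features outside the gene comparison, the greatest called rise was 2.33 and the deepest called fall -2.88 on the log2 scale. That rise exceeded the 1.86 of KRTAP1-5, the greatest among the named genes. These features carry no single gene name here.

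With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 1727 genes with limma (3957 at an unadjusted p under 0.05) and the highest of the other splits 0 (1326 at an unadjusted p under 0.05); at 2-fold the counts were 46 and 0, so in each case 1 of the 10 splits, the real one, gave a result as large. The total number of calls moved by at most 1.09 times over 3 further normalizations, which argues against a normalization offset as the source of that total only. An offset can trade higher calls for lower ones and leave the total alike. Centring gave 726 higher and 855 lower, against 1010 and 717, and kept 1439 of the 1727 calls. For the gene lists 7 of the 10 splits gave as many as the real 4, and the highest other split gave 14, so chance is not excluded for the number of lists shifted. The lists shifted in that split may point to a structure among the arrays beyond the 2 groups, or to a preset correlation of 0.01 that is too low for these lists, since with an estimated correlation the real split gave 0; which of these holds was not tested.

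Genes past the threshold came in runs along the chromosomes, and 69.2% of called genes changed in the same direction as the next called gene on the chromosome, against 48.9% to 53.8% in 1000 shuffles of the directions. Related neighbours measured more than once, or a trend with expression level, are argued against as the sole source of the runs, since the share was 67.9% at a distance of 10 or more tested genes and 68.1% after the trend was removed. A regional difference in copy number or chromatin between the stable line and the control cells may contribute. After the regional median was removed, 64.6% of the called genes stayed called, so a shift shared by the 40 nearest tested genes does not account for those. Shorter regional differences, or larger effects on single genes, are not removed by that median, so the test cannot exclude them. A regional pattern that arrays share in general also stays open, although genes of control array 3 that differed most from the other controls shared direction in 56.4%, the excess of the called genes over the shuffled median was 17.7 points against at most 11.3 points over the 6 comparisons of an array with the other 2 of its group, and the regions held 826 genes against at most 288. The bound set beforehand rested on 1 array and on genes picked by a test against genes picked by size, and with all picked by size the excess was 14.6 points with 3 arrays against 3 and 11.99 to 18.4 points over 18 comparisons of 1 array with 2 of the other group, all of them above 11.3 but the lowest by less than the shuffled range's width of 4.88 points.

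Control array 3 stood apart from the other controls, with scores of 4.72 on component 1 (the others 14.5 and 17.9) and -17.4 on component 2. RNA of the overexpression line mixed into it is argued against. Over 64 genes that differed at least 2-fold between overexpression and control arrays 1 and 2, the fraction of the way that control array 3 had moved had an interquartile range of 0.796, and GABRA3 lay at 0.0481. The inflammatory list differed from the other controls by a median of -0.59 on that array (-0.06 to 0.08 in random lists matched on expression), which restates the low inflammatory genes that drew attention to it and decides nothing about why the array stood apart. MAPK genes and collagens were lower there and G2/M and S-phase genes higher, and no biological explanation was tested.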

How the results depend on the processing

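The regional median was removed as an alternative chosen after seeing the data. GUCY1B3 stayed higher in every alternative (0.59 to 0.75), with an adjusted p between 0.00112 and 0.0293 except 0.0785 for a difference of 0.68 with the ordinary equal-variance test. No named difference past the threshold and no median of the 4 shifted lists changed sign, but of the medians of all lists, 14 changed sign with centring, 10 with quantile and 12 with cyclic loess normalization, and the balance of calls turned with centring, which gave 726 higher and 855 lower. Of 102 named genes past the threshold, 33 kept their side in every alternative that tested them and 69 lost it in at least 1, 19 of them with the regional median removed. The labels do not say whether the replicate numbers pair the arrays. Same-numbered arrays had deviations correlated at 0.282, -0.0971 and -0.241, which with 3 arrays per group cannot decide it. The replicate block, with fewer degrees of freedom, gave 589 higher and 439 lower genes, 998 of them shared with the main 1727. The ordinary test, which borrows no spread across genes, gave 246 higher, 170 lower and 19 lower at least 2-fold. Array weights, which gave control array 3 0.297, gave 1844 higher, 1396 lower and 9 lists. A threshold of 0.01 gave 305 higher and 224 lower. All features as deposited gave 657 higher, 26 at least 2-fold higher, 63 at least 2-fold lower and 7 lists. Without the regional median 630 were higher, and 1115 calls were shared. Leaving out 1 array at a time gave 306 to 2053 higher, 215 to 1577 lower, 6 to 10 at least 2-fold higher and 29 to 53 at least 2-fold lower genes, and 1 to 10 lists. Without overexpression arrays 1, 2 and 3 the counts were 334 and 215, 306 and 262, and 433 and 297; without control array 1 they were 562 and 460, and without control array 3 2053 and 1577, which held all 1727 main calls. The 10 lists without control array 3 were the 4 and those of inflammatory, hypoxia, histone, matrix glycoprotein, G2/M and S-phase genes.

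The lists shifted were 4, against 2 with the block, centring, quantile, cyclic loess or the regional median removed, 0 with an estimated correlation and 1, the NO-cGMP pathway, with fry. The MAPK median was -0.16 with the block, -0.18 with the stricter filter, -0.19 centred, -0.14 quantile, -0.16 cyclic loess and -0.18 with the regional median removed, each past the threshold no longer. The receptor list, likewise, was -0.13 with the block or the mean of probe sets, -0.0051 with all features, -0.16 centred, -0.12 quantile, -0.13 cyclic loess and -0.11 with the regional median removed. With no filter on dim probe sets the receptor median was -0.030, still past the threshold (camera adjusted p = 0.0341). With an estimated correlation or fry the medians stayed 0.21 for cholesterol, 0.16 for p53, -0.16 for MAPK and -0.13 for receptors, without a call. Leaving out an array, the medians ran from 0.18 to 0.29 for cholesterol, 0.16 to 0.20 for p53, -0.26 to -0.060 for MAPK and -0.14 to -0.10 for receptors. The p53 call was lost without overexpression array 2 (0.17). The trend and robust fit and the ordinary test gave no list test. Where no reason is given, the cause was not tested. No detection call was used, so the signal over background that limits dim genes was not measured.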

Other observations

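The lysosomal list, the symbol families, the SNORD116 cluster and the genes named from them were chosen after their values were seen. Lysosomal genes were shifted upward in a list test whose p-values, unlike those of the fixed lists, were not adjusted over lists. A list of 51 genes, drawn up after CTSK and GPNMB were seen among the greatest rises and leaving those out, had 45 tested members, of which 10 rose and 0 fell, with a median of 0.10 (camera p = 0.000942, and p = 0.0166 with an estimated correlation). CTSF, a cathepsin, rose from 5.68 ± 0.06 to 6.28 ± 0.10, cathepsin Z, CTSZ, by 0.38, the acid ceramidase ASAH1 by 0.34, the protective protein CTSA by 0.28 and the cholesterol transporter NPC1 by 0.27. After the arrays were centred the median was 0.07, with 5 higher and 1 lower, and without control array 3, 16 were higher and 2 lower. The hypothesis that lysosomal genes rose as a class in the stable line may hold, as a result found and tested on the same arrays.

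Some families of small noncoding RNAs were lower. Among 198 symbol families with at least 10 tested genes, that named RNU, mostly genes and pseudogenes of spliceosomal RNAs, had the smallest camera p. Of 80, 0 rose and 18 fell, with a median of -0.25 (camera adjusted p = 7.76e-13 over the families, and 0.997 with an estimated correlation), and without control array 3, 34 were lower and 0 higher. Their median was -0.28 after centring, -0.25 with quantile and -0.26 with cyclic loess normalization. Some of these probe sets held identical values, and the 18 that fell held 16 distinct sets of values. Apart from RNU5A-1, RNU11 and RNU6ATAC2P, the members that fell were all copies of U6. RNU6-1, RNU6-11P and RNU6-37P read the same values, so these copies are not independent measurements. No RNU1, RNU2, RNU4 or RNU12 member passed the threshold, so the calls alone do not show a fall across spliceosomal RNAs. All tested RNU1, RNU2 and RNU4 members nevertheless had differences below 0, from -0.51 (RNU4-2, limma, adjusted p = 0.0615) to -0.03 (RNU4-8P). RNU12 (0.14) and RNU12-2P (0.12) lay above 0. A fall outside U6 is therefore neither shown nor excluded. The 4 members named after U7, the RNA of histone processing, all carry pseudogene symbols. They had differences from 0.00050 (RNU7-67P) to 0.47 (RNU7-80P), none of them past the threshold. RNU6-7 fell from 9.19 ± 0.06 to 8.73 ± 0.05. Of 51 SNORA genes 0 were higher and 3 lower, or 2 and 12 without control array 3, with a median of -0.12 (camera adjusted p = 0.00123, and 0.997 with an estimated correlation). Of 200 ribosomal RNA genes and pseudogenes with symbols such as RNA5SP162, 4 were higher and 23 lower, against 1 and 22 after centring and 12 and 29 without control array 3, with a median of -0.03 (camera adjusted p = 0.0290, and 0.997 with an estimated correlation). That median was -0.064 after centring, -0.051 with quantile and -0.056 with cyclic loess normalization. Of 71 SNORD genes 12 were higher and 6 lower, or 15 and 12 without control array 3, with a median of -0.04 (camera adjusted p = 0.601). Of 405 microRNA genes 11 were higher and 1 lower, against 6 and 3 after centring and 22 and 15 without control array 3.

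Within the SNORD family, the imprinted SNORD116 cluster on chromosome 15 was higher. Of 9 tested members, chosen after their values were seen, 8 rose and 0 fell, by a median of 0.57, and all 9 had the overexpression arrays above the control arrays. After centring 7 were higher, with quantile or cyclic loess normalization 6, and without control array 3, 8. SNORD116-24 rose by 0.76 (limma, adjusted p = 0.00227) and SNORD116-17 by 0.73. These copies resemble each other, so their probe sets are not independent.

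GUCY1B3 did not rise together with its neighbours. The 40 tested genes nearest to it on chromosome 4 had a median difference of 0.01, or 0.0106, against 0.68 for GUCY1B3 itself, so a gain of the surrounding chromosome region is argued against as the source of its rise.

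Control array 3 also lay apart from the other controls in single inflammatory genes. CXCL8 read 9.04, 7.81 and 4.79 on control arrays 1 to 3 and 5.14, 5.28 and 5.43 on the overexpression arrays, a difference of -1.93 (limma, adjusted p = 0.218). CSF3 read 10.91, 10.47 and 7.78 against 8.26, 8.14 and 8.83 (adjusted p = 0.295). IL1B read 10.38, 10.33 and 7.86 against 9.34, 9.41 and 10.31 (adjusted p = 0.910). GABRA3, ZNF512 and the adenylate cyclase ADCY8 differed little among the controls, with control array 3 at 8.30, 7.18 and 6.92. CXCL8, CSF3, IL1B and ADCY8 were chosen after their values were seen.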
